A study of Mus musculus with 6 samples.

How the data were processed

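RNA from RAW264.7 cells in 6 samples, 3 labelled as Ep300 siRNA and 3 as control siRNA, was sequenced as stranded mRNA libraries. Per the labels, cells were transfected at 50 nM for 48 h, RNA was extracted with TRIzol, and 2 µg of total RNA went into each library. The deposited table holds raw read counts per gene symbol, one column per library, and its columns were matched to samples by their names. Per the submitters' processing notes, fastp 0.23.4, STAR 2.5.3a, featureCounts and edgeR 3.12.1 were used with the GRCm38 genome. The version of featureCounts, its strand and multimapping settings, the annotation and any use of molecular identifiers are not given in the sources used here. Among counts of 1 to 4, from 79.8% to 80.9% were even in each library, a pattern that counting both mates of each read pair gives. Counts were analysed as deposited, and a test on halved counts was added as an alternative.

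The table held 49492 rows, of which 47229 symbols were found in GENCODE M21 (GRCm38) and 47686 after RefSeq synonyms were added. The symbols of 11 rows had been turned into dates. Coordinates, biotypes, transcript lengths and 3′ UTRs were taken from GENCODE M21. Total counts ranged from 29993567 to 45377510 per library. PCR reads are not independent molecules, so counts give an upper limit on precision.

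Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with the group, TMM scaling, and the quasi-likelihood F-test of Ep300 siRNA against control siRNA with no covariate. P-values are two-sided and were adjusted by Benjamini-Hochberg over the 15741 genes tested, with 0.05 as the threshold. Standard errors were taken from the log2 fold change and the F statistic, and 95% intervals use the test's degrees of freedom. CPM values use TMM-scaled library sizes. The biological coefficient of variation was 8.6%. Shares and values per library give the spread of 3 libraries per group.

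A total of 21 gene lists was fixed before the data were examined, 19 on biology and 2 on quality. They were tested with limma 3.58.1: camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over lists with at least 5 members tested. Camera with an estimated correlation, camera on ranks and fry were alternatives. The genes named were also set by a rule fixed before the data were examined. They are Ep300 and Crebbp, and the 6 largest rises and 6 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 CPM and the groups fully apart, leaving out predicted genes, pseudogenes and accession-style symbols. From each list the rule also takes the member with the smallest p in each direction past the threshold, or the smallest p where none passes. Other list members are given as values. A gene that the rule picked is not reported here.

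On simulated counts for 15505 genes with 50 genes at each fold, the edgeR step recovered 58% of genes changed 1.5-fold, 76% at 2-fold, 86% at 4-fold and 98% at 8-fold. Of its 174 calls, 15 were genes not changed. A planted list gave a camera p of 3.64e-24 and an unchanged list 0.332. The simulated genes were drawn independently, so this does not test camera on lists whose members are correlated.

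Alternatives were RLE, upper-quartile and library-size scaling, no filter on low counts, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, DESeq2 1.42.0, limma-voom, each library left out in turn, and stricter thresholds. Other splits of the 6 libraries, a trend on GC content and transcript length, and 7-base sequences in 3′ UTRs were also examined. For the last, each of 15662 7-mers found in at least 100 of 11761 3′ UTRs was tested by regression, with UTR length and GC content as covariates, on log2 fold changes and on signed z-scores from edgeR's p. The siRNA sequence set against the rises was recalled from general knowledge of a common control, not taken from the study. On simulated data the regression recovered 5 of 5 planted 7-mers. That step used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures used matplotlib 3.10.9.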

Results

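Gene expression was measured by stranded mRNA sequencing in RAW264.7 cells, a mouse macrophage line. Cells were collected 48 h after transfection with 50 nM of an siRNA against Ep300 or of a control siRNA. Ep300 encodes p300, a lysine acetyltransferase and transcriptional coactivator. Each group held 3 libraries, and the comparison asked how macrophage gene expression differed after Ep300 silencing. Total counts were 29993567, 35079257 and 37132333 in Ep300 siRNA replicates 1, 2 and 3, and 45377510, 36018207 and 35930658 in control siRNA replicates 1, 2 and 3. Counts of libraries of one group did not agree within sampling noise (chi-square per degree of freedom of 10.2 to 37.3), and each was counted as a replicate, as labelled. PCR copies and the counting of both mates of a pair raise that value too, so it does not show separate cultures. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

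Ep300 (GRCm38 chromosome 15, 81585351 to 81652077, plus strand) fell to 0.485 of its control level. Its mean was 55.0 ± 3.94 CPM (count scaled by library size; SD, n = 3) after Ep300 siRNA and 113.5 ± 6.02 CPM (SD, n = 3) after control siRNA. The 3 Ep300 siRNA libraries held 51.1, 59.0 and 55.0 CPM and the 3 control libraries 106.8, 115.3 and 118.4 CPM. The log2 fold change was −1.04 ± 0.07 (SE, 95% interval −1.20 to −0.89, edgeR adjusted p = 3.62e-05). Crebbp, the paralog of Ep300, was at a log2 fold change of 0.14 ± 0.08 (SE) and did not pass the test (edgeR adjusted p = 0.293).

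**Figure D1:**
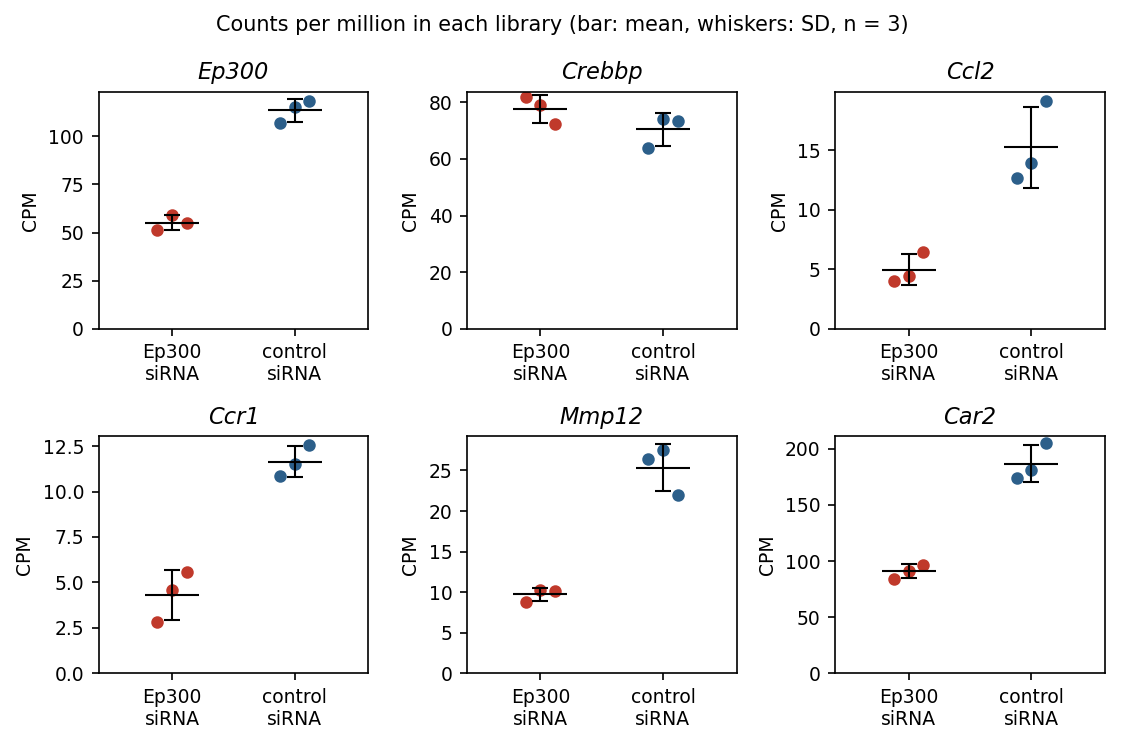
CPM of 6 genes in each library of the Ep300 siRNA and control siRNA groups; points are libraries, bars are means and whiskers are SD (n = 3). Ep300 was at 51.1 to 59.0 CPM after Ep300 siRNA and at 106.8 to 118.4 CPM after control siRNA, and Ccl2, Ccr1, Mmp12 and Car2 were also lower in all 3 Ep300 siRNA libraries.

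Among genes that met the naming rule, which asks for a mean of at least 5 CPM and leaves out predicted genes, the largest fall was that of Ccl2. This chemokine, which attracts monocytes, fell to 0.33 of its control level (4.98 ± 1.29 against 15.2 ± 3.42 CPM, SD, n = 3). Ccr1, a chemokine receptor, fell to 0.374 (4.31 ± 1.40 against 11.7 ± 0.864 CPM) and Mmp12, the macrophage elastase, to 0.384 (9.71 ± 0.852 against 25.3 ± 2.92 CPM). Under the same rule, the largest rises were smaller and led by Rmdn2 (1.89-fold), Ctnnbip1 (1.74-fold), an inhibitor of beta-catenin, and Hap1 (1.73-fold). They were followed by Taldo1 (1.72-fold), an enzyme of the pentose phosphate pathway, Ei24 (1.68-fold) and Cnnm2 (1.65-fold). The rise of Ctnnbip1 was uneven, with 27.2, 18.1 and 13.8 CPM in Ep300 siRNA replicates 1, 2 and 3. Its log2 fold change of 0.796 was 0.505 at the lowest with 1 library left out. 

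Strap fell to 0.395 of its control level (log2 fold change −1.34 ± 0.09, SE) and Cct6a, a subunit of the cytosolic chaperonin, to 0.432 (log2 fold change −1.21 ± 0.08, SE). The Cct6a and Strap transcripts each matched 14 of 19 bases of the same stretch of the Ep300 mRNA. Only the 7 stretches with a candidate seed site near their end were compared. In each transcript, 6 of the 7 bases of the candidate site in that stretch were matched. Of random pairs of mRNAs, 2.1% shared a match of 14 or more bases to such a stretch. The share for any stretch of the Ep300 mRNA was not computed. Cct6a and Strap were picked from the largest falls and the candidate sites from the same fold changes, and the 2.1% allows for neither choice. Ptgs2os2, annotated as a lincRNA near Ptgs2, fell to 0.437, from 8.01 ± 0.593 to 3.48 ± 0.706 CPM (SD, n = 3). The use of strand in the counting is not given in the sources used here, so reads of Ptgs2os2 cannot be told apart from those of an overlapping gene on the other strand. Of these 6 rises, the 3′ UTRs of Taldo1, Ei24 and Cnnm2 held at least 1 of the sites CGGAGAA, TCGGAGA and TGTCACG, of which the first was picked from the rises themselves and the others after it was seen. The edgeR adjusted p of these 12 genes ran from 3.62e-05 (Strap and Cct6a) to 0.0304 (Ctnnbip1).

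Across 15741 genes tested, 1068 (6.78%) changed at an edgeR adjusted p under 0.05, of which 435 rose and 633 fell. Most changes were small: the median change was 1.27-fold among genes that rose and 0.75-fold among genes that fell. At least 2-fold changes were seen for 51 genes that fell and for 1 that rose, Nr4a3, an orphan nuclear receptor (0.991 ± 0.119 to 2.19 ± 0.681 CPM, SD, n = 3). For all 1068 genes the 3 libraries of one group lay above the 3 of the other. These genes were called on the same libraries, so that separation adds no support. Of the 15741 genes tested, the groups lay apart for 4324, where chance gives 10%. Without scaling factors, on library sizes alone, 316 genes rose and 788 fell, against the 435 and 633 with TMM scaling. By DESeq2, 693 rose and 743 fell. Leaving out one library changed the count to between 490 (without control siRNA replicate 2) and 1054 (without control siRNA replicate 1).

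**Figure D2:**
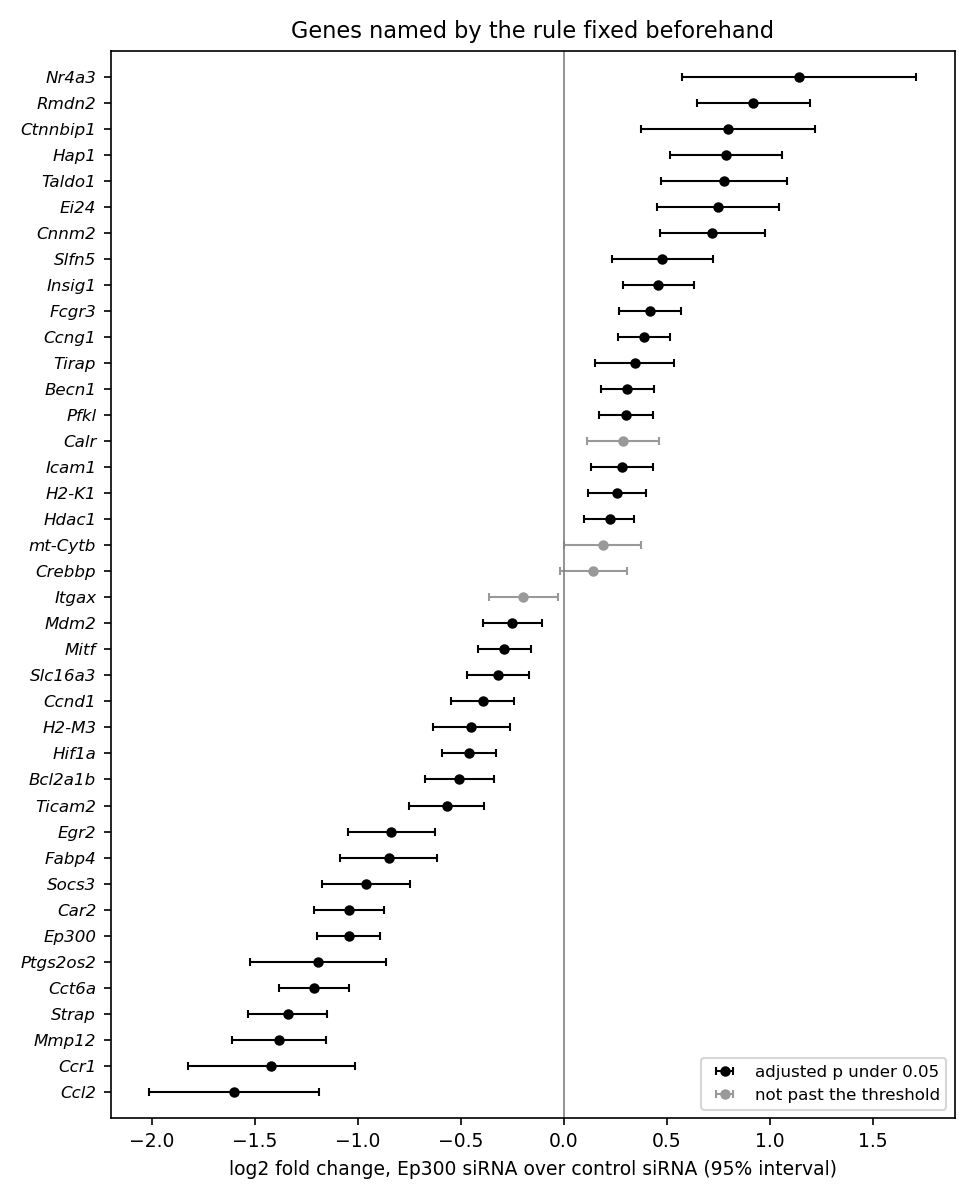
Log2 fold changes (Ep300 siRNA over control siRNA, n = 3 per group) of genes named by a rule fixed beforehand; points are edgeR estimates, bars are 95% intervals, and grey marks genes not past the adjusted p threshold. Falls reached a log2 fold change of −1.60 (Ccl2) and rises 1.14 (Nr4a3).

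The chemokine and inflammatory lists were lower by the list test with its preset correlation. All 16 measured chemokines and chemokine receptors had negative log2 fold changes (median −0.53), and 6 of them fell, with none rising. Adjusted over the list alone, 9 fell. Besides Ccl2 and Ccr1, values were −1.28 ± 0.25 (SE) for Ccl5, −0.58 ± 0.11 for Ccl9, −0.54 ± 0.09 for Cxcl2 and −0.41 ± 0.07 for Ccl3. The chemokine list passed limma's camera test against all other genes (adjusted p = 2.98e-06; adjusted p = 0.343 with an estimated correlation). Of 16 inflammatory cytokines and mediators, 4 fell and none rose (5 fell adjusted over the list alone), with a median of −0.42 (−0.26 with a filter of 1 CPM in 3 libraries). The clearest was Hif1a, a transcription factor of the hypoxia response, at 139.4 ± 4.54 against 192.0 ± 7.95 CPM (SD, n = 3; log2 fold change −0.46 ± 0.06, SE). Ptgs2, the inducible cyclooxygenase, was at −0.73 ± 0.10 (SE) and Il1rn, the interleukin-1 receptor antagonist, at −0.72 ± 0.12. The cytokine Tnf did not pass (132.0 ± 25.8 against 142.8 ± 4.18 CPM, SD, n = 3; edgeR adjusted p = 0.622). Neither did Il1a, Il1b and Il6, at means of 0.26, 0.91 and 0.30 CPM over all libraries. The inflammatory list passed camera at an adjusted p of 0.00648 (adjusted p = 0.343 with an estimated correlation).

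Of 24 NF-kB target and feedback genes, 2 rose and 6 fell (3 and 9 adjusted over the list alone; median −0.12). Bcl2a1b, one of several near-identical anti-apoptotic genes between which reads can be split, fell to 0.704 of its control level. Icam1, an adhesion molecule, rose 1.22-fold. The list fell by camera (adjusted p = 0.0318; adjusted p = 0.54 with an estimated correlation), a call lost without Ep300 siRNA replicate 1 or without control siRNA replicate 2 or 3 (adjusted p up to 0.129). Of 24 genes of Toll-like receptor signalling, 1 rose and 4 fell (3 and 5 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.592). The adaptor Ticam2 fell to 0.674 and the adaptor Tirap rose 1.27-fold. Tlr4, the receptor for lipopolysaccharide, was at −0.32 ± 0.06 (SE).

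Of 16 genes that osteoclasts use, a fate RAW264.7 cells can take, 7 fell and none rose (9 fell adjusted over the list alone; median −0.35). Car2, a carbonic anhydrase, fell from 186.8 ± 16.4 to 90.7 ± 6.26 CPM (SD, n = 3; log2 fold change −1.04 ± 0.08, SE). Mmp9 was at −1.23 ± 0.23 (SE), Acp5 at −1.10 ± 0.20 and Ctsk at −0.52 ± 0.12. The camera adjusted p was 2.39e-06 (adjusted p = 0.343 with an estimated correlation). Of 10 measured markers of alternative activation, 3 fell and none rose (4 fell and 1 rose adjusted over the list alone; median −0.41). Socs3, a feedback inhibitor of cytokine signalling, fell from 11.1 ± 0.430 to 5.70 ± 0.0324 CPM (SD, n = 3). Arg1, Retnla and Chil3, common markers of that state, were too low to test, with at most 7 counts in any library. The list's median was −0.219 without control siRNA replicate 1 and −0.261 without control siRNA replicate 3. It passed camera at 0.0209 (adjusted p = 0.343 with an estimated correlation), a call lost without replicate 2 of either group (adjusted p up to 0.0789) and by camera on ranks (adjusted p = 0.073).

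Of 26 immediate-early and CREB target genes, 7 fell and 1 rose (9 and 2 adjusted over the list alone), but the list as a whole did not pass (camera adjusted p = 0.217). Its median log2 fold change was 0.01 and its mean −0.05, with a downward test. Egr2, a zinc-finger transcription factor, fell to 0.56 of its control level, and Nr4a3 was the gene that rose. Jun was at −0.43 ± 0.06 (SE), Fos at −0.55 ± 0.11 and Dusp1 at −0.58 ± 0.12.

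Of 41 DNA replication and cell division genes measured, 40 had negative log2 fold changes (median −0.19). Over all genes 7 fell, none rose and 34 did not pass, and adjusted over the list alone 23 fell. Ccnd1, the G1 cyclin D1, fell from 329.0 ± 18.5 to 250.4 ± 16.9 CPM (SD, n = 3). Myc was at −1.04 ± 0.22 (SE), E2f2 at −0.50 ± 0.10 and Ccnb1 at −0.41 ± 0.09. The camera adjusted p was 1.11e-08 (adjusted p = 0.409 with an estimated correlation). The list's median per library was −0.24, −0.24 and −0.11 in the Ep300 siRNA libraries and −0.03, −0.04 and 0.06 in the control libraries. Of 22 p53 target genes, 3 rose and 1 fell (5 and 2 adjusted over the list alone; median 0.09, and 0.054 with library sizes alone): Ei24 and Ccng1 (1.31-fold) rose, and Mdm2, the ubiquitin ligase of p53, fell to 0.841. The p53 list rose by camera (adjusted p = 0.037; adjusted p = 0.343 with an estimated correlation), a call lost without Ep300 siRNA replicate 2 or 3 or control siRNA replicate 1 (adjusted p up to 0.109) and with a filter of 1 CPM in 3 libraries (adjusted p = 0.053).

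**Figure D3:**
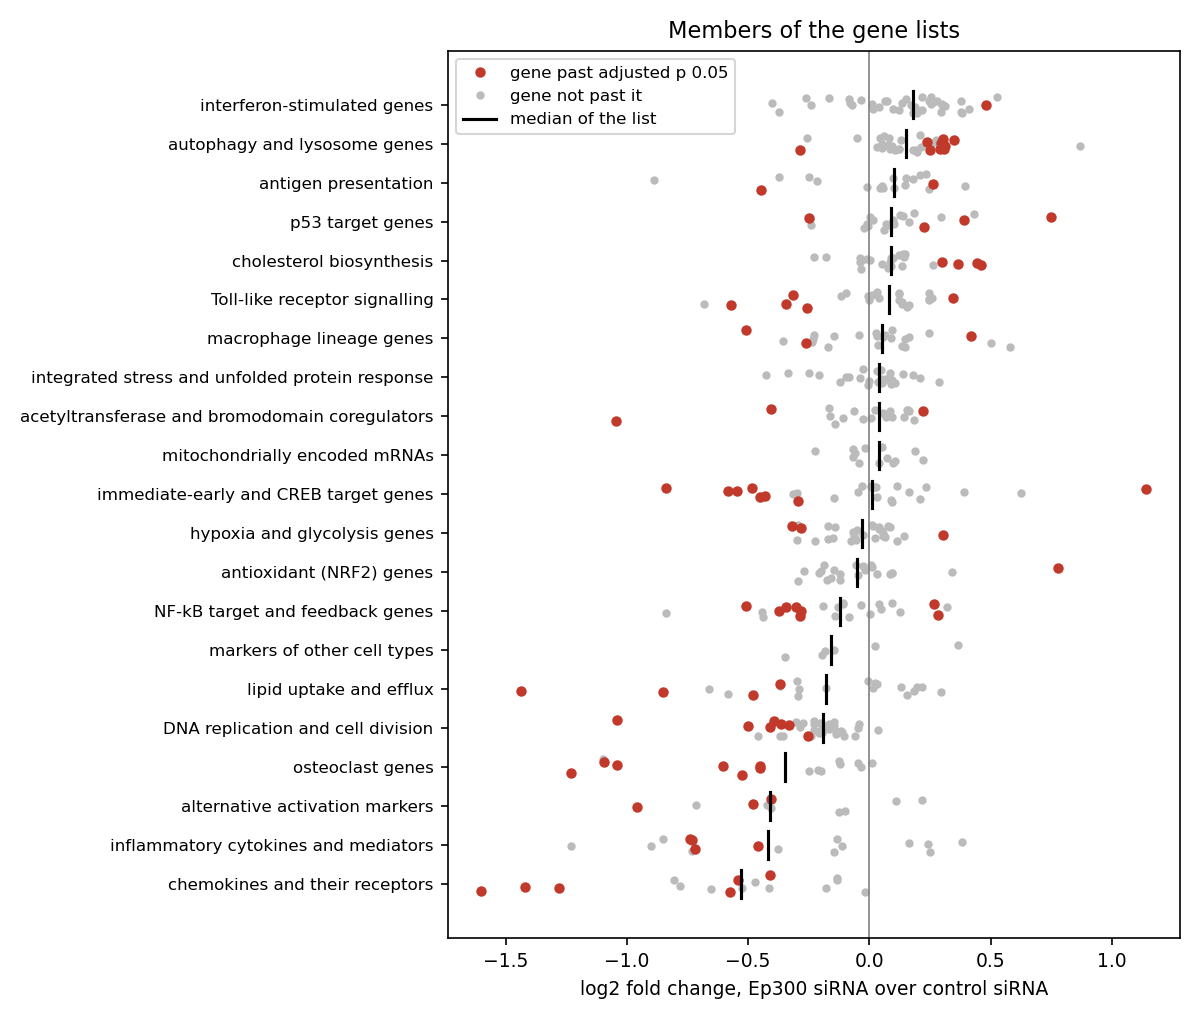
Log2 fold change (Ep300 siRNA over control siRNA) of each measured member of 21 gene lists, ordered by median; red points passed the edgeR adjusted p threshold and black bars are list medians. Medians ran from −0.53 for chemokines and their receptors to 0.18 for interferon-stimulated genes.

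Of 34 autophagy and lysosome genes, 8 rose and 1 fell (13 and 1 adjusted over the list alone), and 31 had positive log2 fold changes (median 0.15). Becn1, which starts autophagosome formation, rose 1.24-fold (107.3 ± 2.27 against 86.6 ± 3.86 CPM, SD, n = 3). The lysosomal proteases Ctsl and Ctsz were at 0.31 ± 0.07 and 0.29 ± 0.07 (SE). Mitf, a transcription factor that controls lysosomal genes, fell to 0.819. The camera adjusted p was 4.59e-06 (adjusted p = 0.409 with an estimated correlation). The list's medians were 0.22, 0.12 and 0.13 in Ep300 siRNA replicates 1, 2 and 3, and 0.04, 0.02 and −0.07 in the controls.

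Of 24 cholesterol biosynthesis genes, 4 rose and none fell (4 rose adjusted over the list alone; median 0.09). Insig1, a sterol-regulated inhibitor of the pathway, rose 1.37-fold. The list rose by camera (adjusted p = 0.0318; adjusted p = 0.859 with an estimated correlation), a call lost without Ep300 siRNA replicate 1 or without control siRNA replicate 2 or 3 (adjusted p up to 0.328). Its median was 0.17, 0.02 and 0.01 in Ep300 siRNA replicates 1, 2 and 3, and 0.06, −0.01 and −0.04 in the controls. The median log2 fold change was 0.028 without Ep300 siRNA replicate 1 and 0.054 with library sizes alone. Of 21 genes of lipid uptake and efflux, 4 fell and none rose (7 and 1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.193). Fabp4, a fatty acid binding protein, fell to 0.555 of its control level. Abca1, the cholesterol exporter, was at −1.44 ± 0.24 (SE), and Apoe was at −0.48 ± 0.12.

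Interferon-stimulated genes varied with the library. Of 40, 1 rose, Slfn5 (1.39-fold), and none fell, with the same counts adjusted over the list alone. The list's medians were −0.26, 0.39 and 0.33 in Ep300 siRNA replicates 1, 2 and 3, and −0.28, 0.14 and 0.14 in the controls. The median log2 fold change, 0.18, was 0.357 without Ep300 siRNA replicate 1 and 0.059 without replicate 2. The list rose by camera (adjusted p = 0.037; adjusted p = 0.894 with an estimated correlation), a call lost without Ep300 siRNA replicate 2 or 3 or control siRNA replicate 1 (adjusted p up to 0.786) and with a filter of 1 CPM in 3 libraries (adjusted p = 0.053). Of 19 antigen presentation genes, 1 rose and 1 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.486). The class I genes H2-K1 and H2-M3 went opposite ways, to 1.20-fold and 0.733 of control. H2-K1 shares sequence with other class I genes, so its reads may be split between them.

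The macrophage lineage list did not pass, though 11 members had an unadjusted edgeR p under 0.05. Of 24, 1 rose and 2 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.727). Fcgr3, a low-affinity IgG receptor, rose 1.34-fold. Csf1r, the receptor for macrophage colony-stimulating factor, was at −0.24 ± 0.07 (SE). Of 20 acetyltransferase and bromodomain coregulators, 1 rose and 2 fell, Ep300 among them (2 and 2 adjusted over the list alone; camera adjusted p = 0.727); its median was 0.04, its mean −0.04 and the test upward. Hdac1, a lysine deacetylase, rose 1.17-fold.

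Of 29 hypoxia and glycolysis genes, 1 rose and 2 fell (the same adjusted over the list alone; camera adjusted p = 0.6). Pfkl, a phosphofructokinase, rose 1.23-fold, and Slc16a3, a lactate transporter, fell to 0.80. Of 22 antioxidant genes, 1 rose, Taldo1 (1 adjusted over the list alone; camera adjusted p = 0.705). Of 26 genes of the integrated stress and unfolded protein response, none passed edgeR's adjusted p, 8 had an unadjusted p under 0.05, and 5 passed by DESeq2 and 2 by limma-voom (0 adjusted over the list alone; camera adjusted p = 0.592). Calr, an endoplasmic reticulum chaperone, was at 0.29 ± 0.08 (SE; edgeR adjusted p = 0.0522).

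Of 37 markers of other cell types, 6 were high enough to test; none passed edgeR's adjusted p, 2 had an unadjusted p under 0.05, and 0 passed by DESeq2 or limma-voom (0 adjusted over the list alone; camera adjusted p = 0.705). Itgax, a dendritic cell marker that macrophages also express, was at −0.20 ± 0.08 (SE). Of 13 mitochondrially encoded mRNAs none passed edgeR's adjusted p, 1 had an unadjusted p under 0.05, mt-Cytb (0.19 ± 0.08, SE), and 0 passed by DESeq2 or limma-voom (0 adjusted over the list alone; camera adjusted p = 0.717). Ep300 siRNA replicate 1 held the most counts of Gm42418, a gene that overlaps ribosomal RNA sequence, at 5691 CPM against 1322 to 2148 CPM in the other libraries. It also lay farthest out on the first principal component, which took 32.9% of the variance, at −29.7 against −13.8 and −8.9 for the other Ep300 siRNA libraries and 16.8 to 18.8 for the controls.

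Of the 21 lists, 10 passed camera with its preset correlation (4 higher, 6 lower). None of the 10 passed with an estimated correlation (2 had an unadjusted p under 0.05). By fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, 5 lists passed: inflammatory genes, chemokines, alternative activation markers, p53 targets and osteoclast genes. Of the 36 genes besides Ep300 that passed and were picked by the rule fixed beforehand, 11 lost their call when some library was left out (edgeR adjusted p up to 0.163): Ctnnbip1, H2-K1, H2-M3, Hdac1, Icam1, Mdm2, Mitf, Nr4a3, Slc16a3, Slfn5 and Tirap. Mdm2 and Tirap lost it with each of the 6 libraries left out in turn. With library sizes alone, Icam1 (edgeR adjusted p = 0.0501), Tirap (0.0525), H2-K1 (0.0634) and Hdac1 (0.075) lost it too, as did Hdac1 with no filter on low counts (0.0516) and Ctnnbip1 by limma-voom (adjusted p = 0.057).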

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

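The settings with halved counts and without mitochondrial and Gm42418 rows were chosen only after the data were seen. Ep300 stayed past the threshold in every setting run. Counts of changed genes rose to 1721 (730 higher, 991 lower) with no filter on low counts, which tests 30207 genes. DESeq2 called 1436 genes, 693 higher and 743 lower, and 1038 of the 1068 main calls were among them; the cause of its higher number of rises was not tested. With an adjusted p under 0.01, 369 genes remained past it (130 higher, 239 lower), and with at least 2-fold change 52 (1 higher, 51 lower). Leaving out one library gave 490 to 1054 changed genes, 202 to 447 higher and 280 to 607 lower, with fewer samples in each fit. Without control siRNA replicate 2 the count was 490, and 480 of the main calls were among them; without Ep300 siRNA replicates 1, 2 and 3 it was 698, 533 and 696, and without control siRNA replicate 3 it was 593. Other scalings, the 1 CPM filter, limma-voom, halved counts and removal of mitochondrial rows gave 1043 to 1113. The 10 gene lists called fell to 0 with an estimated correlation, to 5 by fry and to 8 with the 1 CPM filter, and were 7 to 10 with a library left out. Correlations of same-numbered deviations were 0.087, 0.02 and −0.047 for replicates 1, 2 and 3. Only replicate 1 correlated best with its own number. The second principal component took 20.8% of the variance. On it, Ep300 siRNA replicate 1 (19.6) and control siRNA replicate 1 (18.7) lay apart from the other libraries (−21.1 to −2.3). A batch shared by the libraries numbered 1 therefore stays open, and the main fit had no block for it. The replicate block gave 1357 changed genes (580 higher, 777 lower). No named gene and no list called in the main test changed sign; 13 medians of 5 lists that were not called did, most often immediate-early and CREB target genes (0.007, but −0.027 with library sizes alone and −0.011 with the 1 CPM filter). For named genes 584 comparisons kept their side of the threshold, 50 lost it and 5 gained it, and for lists 319, 32 and 3. With 3 libraries per group, the self-test recovered 58% of genes changed 1.5-fold, so smaller changes than that were often not detectable.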

Other observations

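The tests on signed z-scores, on both strands of an siRNA, on seven-base sites as the whole cause, on Cct6a and Strap, and on the antisense strand of a common control siRNA were chosen only after the result was seen. The siRNA sequences are not given in the sources used here.

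Among the 633 genes lower after Ep300 siRNA, the test set beforehand, the lowest t of a 3′ UTR 7-mer on log2 fold changes, gave −6.07 (ATTCTCA, in 1518 UTRs), short of the −8 asked for and passed in size by 4 other splits, whose sign is arbitrary (absolute t of 6.17 to 7.34). The comparison with other splits was a poor bound, since their values came from GCCGCAA and CGATATC, found in only 122 and 114 UTRs, and since those splits keep part of the real contrast; on signed z-scores, a test added later, AATTCTC reached −8.39 and TGCAGTC −7.45, beyond the largest absolute t of 4.98 over 20 shuffles of the genes, while TATCATG (−4.98) only equalled it. The 19-base stretch of Ep300 mRNA GGACTGCAGTCTATCATGA (bases 5458 to 5476) carries sites for the seeds of both strands of a duplex, TATCATG and TGCAGTC, and 0.16% of other mRNAs of like length (1 of 635) held a stretch with as low a summed t (−12.42), so off-target binding may account for part of the falls. For Cct6a and Strap this stays open. Both matched 14 of 19 bases of another Ep300 stretch, GCACCGAAGTGAATTCTCA (bases 4105 to 4123). Only the 7 Ep300 stretches with a candidate site near their end were compared. Of 1000 random pairs of mRNAs, 2.1% shared a match of 14 or more bases to such a stretch. That share does not allow for the choice of this pair from the largest falls, nor of candidate sites from the same fold changes. In each gene 1 of the 7 bases of the candidate site AATTCTC was not matched, and Strap held no site in its 3′ UTR. No 3′ UTR was searched for Cct6a, whose symbol matched a gene annotated as a processed transcript. Of the 583 genes lower searched, 42.5% held AATTCTC, TGCAGTC or TATCATG in the 3′ UTR (29.5% of uncalled genes at the same UTR lengths). This share argues against those exact sites as the whole direct cause. The count left out the shifted sites ATTCTCA, GCAGTCA and ATCATGA, held by 24.5%, 19.9% and 14.2% of genes lower. How many of those genes lacked a counted site was not examined. Whether 3′ UTR sites of any form were the whole direct cause therefore stays open. Sites elsewhere also stay open. Of the genes lower with a transcript besides Ep300, 12.4% (78 of 628, a wider set) lacked the 6-base cores in their longest transcript. The share of uncalled genes that lacked them was not computed, so this value cannot decide the question. Loss of Ep300 itself is untested, as a single Ep300 siRNA arm cannot part it from off-target effects.

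Among the 435 genes higher after Ep300 siRNA, CGGAGAA had the highest t on signed z-scores (6.79), beyond the 4.98 of the shuffles. The test set beforehand, on log2 fold changes, gave a highest t of 7.72, for CGATATC, above the 7.34 of another split but short of the 8 asked for, and that 7-mer lay in 7 of the genes higher. A widely sold non-targeting siRNA, TTCTCCGAACGTGTCACGT, not named in the labels, was recalled after CGGAGAA was seen, so its sense-strand site TCGGAGA (t = 5.0), which overlaps CGGAGAA, tests nothing. The site of its antisense strand, TGTCACG (t = 3.72), lay below the 4.98 reached by shuffles, though only 0.11% of 7-mers had as high a t. Whether a control siRNA lowered part of these genes in the control libraries stays open. Of the 406 searched, 72 (17.7%) held 1 or more of these 3 sites in the 3′ UTR, a count raised by the choice of CGGAGAA from the same genes. Of uncalled genes 6.2% did and of genes lower 6.5%, shares not matched for UTR length. Sites elsewhere were not examined, and an effect of Ep300 on these genes is untested.

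The low median of DNA replication and cell division genes (−0.194) was not removed by any of 3 corrections. Without Ep300 siRNA replicate 1, the library farthest from the others, the median was −0.163, which argues against that library as the cause. After removal of the trend on GC content and transcript length, which took 0.8% of the variance, it was −0.173, which argues against that trend as the whole cause. Among members without AATTCTC, TGCAGTC or TATCATG in the 3′ UTR, sites picked from these data, it was −0.187. That argues against those 3 sites in the members' own 3′ UTRs as the whole direct cause. Indirect effects of those sites were not tested, and other sites stay open. With the estimated correlation between members of 0.366 the list no longer passed. Slower growth after loss of Ep300 and a difference in culture density between the dishes both stay open, as neither was tested.

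The 10 splits of the 6 libraries are too few for a share under 0.05. By edgeR the real split gave 1068 changed genes (435 higher, 633 lower), and the highest other gave 0, with up to 1007 at an unadjusted p under 0.05, so 1 split, the real one, gave as many. It gave 10 gene lists, and the highest other split gave 11; 3 splits gave as many as the real one, itself included.

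Most members of 4 called lists that fell held none of the 3 seven-base sites in the 3′ UTR. Sites were present in 2 of the 6 chemokine genes that fell, in 1 of the 7 osteoclast genes, in 2 of the 4 inflammatory genes, Hif1a among them, and in 2 of the 7 cell division genes. Of all genes lower searched 42.5% held a site, and of uncalled genes 23.5%. No test compared these counts with those shares. ATTCTCA, GCAGTCA and ATCATGA were not counted as sites. Ccl2, Ccr1, Car2, Socs3, Egr2 and Fabp4 held none, while Mmp12, Ticam2 and Slc16a3 held at least 1. Cnnm2 and Nr4a3, which rose, also held at least 1. The median of members without a site was −0.50 for chemokines and −0.45 for osteoclast genes, and −0.14 for inflammatory genes against −0.42 over all of them. Of the 4 cholesterol genes that rose, 2 held CGGAGAA, TCGGAGA or TGTCACG in the 3′ UTR, Insig1 among them. So did 1 of 3 p53 targets, 1 of 8 autophagy and lysosome genes and 0 of 1 interferon-stimulated genes that rose. The choice of CGGAGAA from the rises themselves raises such counts. Rows that copy mitochondrial sequence (Gm10925, Gm28661 and Gm28437) took 2.1% to 2.38% of counts in each library.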
